A study of Ipomoea batatas with 4 samples.

How the data were processed

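Transcripts and small RNAs were measured in systemic leaves of sweet potato (Ipomoea batatas cv. Tainung 57), that is, leaves other than the wounded one. The 4 libraries fall into 2 transcriptome libraries and 2 small RNA libraries. Each pair holds 1 library from non-wounded plants and 1 library from plants sampled 120 min after wounding. Samples were grouped by their titles, and no label gives a second library for any group.

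Total RNA was extracted with Trizol, per the labels' protocols. The transcriptome libraries were made with an Ovation kit that uses Arabidopsis primers to remove cytoplasmic and mitochondrial rRNA, and the small RNA libraries with an Illumina TruSeq small RNA kit, per the labels' protocols. The assembler, aligner, counter, adapter trimming and read filters are not given in the sources used here.

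The deposited transcriptome tables list 178928 contigs in 107913 components, with a contig's length, its unique read count, its total read count and an RPKM value. Contigs are named in the style of a de novo assembly, per the file headers. The RPKM deposited by the authors equals the total read count per kilobase of contig and per 1000000 of all counted reads for all 178928 contigs, within a relative tolerance of 0.001. The contig names carry no gene symbol or description, and 0 of them occur in the sweet potato gene table used for names. Contigs were therefore reported by number and size of change, with 2 named in each direction. The 23 gene lists, the katanin p80 genes and the targets of miRNA families that were planned for comparison were not analysed here, because they need gene names.

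The deposited small RNA table lists 5571970 distinct tags of 18 to 25 nt with the read count of each tag in each library, and 2426210 of these rows were at 0 in both libraries. A second column deposited by the authors scales each library's counts to a total of 2000000, and it is a fixed multiple of the counts. Tags were not mapped to a genome here, so they are reported by sequence.

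Transcriptome depth was 42681152 counted reads in the non-wounded and 41160924 in the wounded library. Small RNA depth was 4788730 and 4880399 reads, so 1 read was worth 0.209 and 0.205 RPM (reads per 1000000 reads of the table). A count of 0 allows up to 3 reads, or 0.626 and 0.615 RPM. All intervals are exact binomial (Clopper-Pearson) 95% intervals, or the conditional binomial interval of a ratio. They cover counting error only, because reads without molecular identifiers are not independent molecules and no group has a replicate.

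No test between conditions was made, since each condition has 1 library. For contigs the measure was the difference of log2(RPKM + 1), wounded minus non-wounded, among contigs at 1 RPKM or more in either library. Fold changes on this scale understate the change of low contigs. Counting error alone was described by 20 draws in which both libraries came from the pooled read share of each contig. For small RNAs the measure was the ratio of RPM. A miRNA family was the sum of tags of 20 to 22 nt with at most 2 substitutions against a reference mature sequence and ends within 1 nt of it, each tag going to its nearest family. The 29 reference sequences are conserved plant miRNAs written down before the data were examined. A miRNA family is therefore named by sequence similarity, and precursors were not checked.

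The items named in the text were chosen before the data were examined by these rules: the 2 contigs with the largest change in each direction at 5 RPKM or more in the higher library, every miRNA family with 100 or more reads in either library, miR168-3p whatever its count, and the 5 tags of 20 to 24 nt with the largest change in each direction among those with 1000 or more reads in either library. The other tags printed beside a family, to show which tags its ratio rests on, and the tags of the closing section were chosen afterwards.

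The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. They were tested on simulated data. Among 178928 simulated contigs, the changed ones were drawn from those at a pooled mean of 5 RPKM or more. Of these, 100% of the 100 contigs changed 4-fold were found past 2-fold. Of those changed exactly 2-fold 22% were, since the pseudocount shrinks the ratio. Lower contigs were not simulated as changed, although 33244 of the 41549 contigs compared lay between 1 and 5 RPKM in their higher library. Of 5800 simulated miRNA tags with up to 2 substitutions 99.7% returned to their family, and 0 of 20000 random tags were assigned to one. The simulated miRNA tags were made within the limits of the family rule. Their return checks the calculation, not how many real variants the rule finds. The alternatives tried were other pseudocounts and filters, other scalings, other rules for miRNA tags, unique reads, TPM computed from the reads, and contigs summed by component.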

Results

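Transcripts and small RNAs were sequenced from systemic leaves of sweet potato, a storage-root crop of the morning glory family, without wounding and 120 min after wounding. The title of the series names a module of the miRNA miR168-3p and a katanin subunit, KTN80, in jasmonate synthesis. The design asks which transcripts and which small RNAs differ in an unwounded leaf when another part of the plant is wounded. Each of the 4 libraries stands alone in its group, so every difference below compares 2 libraries and has no replicate check. The transcriptome libraries held 42681152 reads (non-wounded) and 41160924 reads (wounded) on 178928 contigs, of which 89.2% and 88.5% were assigned uniquely. The small RNA libraries held 4788730 reads in 1769486 distinct tags (non-wounded) and 4880399 reads in 1790909 distinct tags (wounded).

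The first comparison asked how the systemic leaf transcriptome differed after wounding. Of 41549 contigs at 1 RPKM or more in either library, 2702 were at least 2-fold higher and 1859 at least 2-fold lower in the wounded library on the log2(RPKM + 1) scale. With the median log2 ratio, 0.065, set to 0 these numbers became 2253 and 2269. Among contigs at 5 RPKM or more in either library, where the median was -0.0073 without such a shift, they were 1006 and 731. More of the large differences were upward. At 4-fold or more 451 contigs were higher and 73 lower, at 8-fold or more 147 were higher and 6 lower, and at 16-fold or more 51 were higher and 0 lower. With the median set to 0 the 8-fold numbers were 140 and 6, and the 16-fold numbers 42 and 1. The excess depended on the pseudocount: with 0.1 in place of 1 the numbers were 805 and 267 at 8-fold and 273 and 37 at 16-fold. Counting error alone gave at most 2 contigs past 2-fold in either direction and 0 past 4-fold in 20 draws.

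The 51 contigs that were 16-fold or more higher went from a median of 1.16 RPKM in the non-wounded library to 91.8 RPKM in the wounded library. Together they held 7709 reads without wounding and 324801 reads after it, or 0.0181% and 0.789% of all reads. After wounding 25 of them were at 100 RPKM or more. In the non-wounded library 24 of them were under 1 RPKM and 1 had no read. The 51 contigs came from 29 assembly clusters, and 32 of them lay in 10 clusters that held 2 or more. Contigs of one cluster can share reads, and the contigs were not resolved to genes.

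The contig with the largest difference upward was TR52721_c21_g3_i1 (378 nt), with 31 reads (1.92 RPKM) in the non-wounded and 7753 reads (498 RPKM) in the wounded library. Its read share was 259-fold higher (counting interval 183 to 382). TR52721_c21_g7_i2 (1489 nt), of the same cluster, went from 125 to 29100 reads, or from 1.97 to 475 RPKM, a 241-fold higher share (counting interval 203 to 290). The largest difference downward was in TR44245_c1_g1_i1 (2103 nt), with 25214 reads (281 RPKM) without wounding and 1493 reads (17.2 RPKM) after it, a 16.3-fold lower share (counting interval 15.5 to 17.2). TR63404_c0_g1_i2 (1266 nt) followed on this scale, with 684 reads (12.7 RPKM) and 19 reads (0.365 RPKM), a 34.7-fold lower share (counting interval 22.1 to 58.0). Of the reads of TR52721_c21_g3_i1, 28 of 31 and 6852 of 7753 were unique to the contig. Nearly all reads of TR52721_c21_g7_i2 and TR44245_c1_g1_i1 were, whereas for TR63404_c0_g1_i2 428 of 684 and 9 of 19 were. On the log2(RPKM + 1) scale both falls were under 16-fold. The genes behind these contigs were not identified here.

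**Figure D1:**
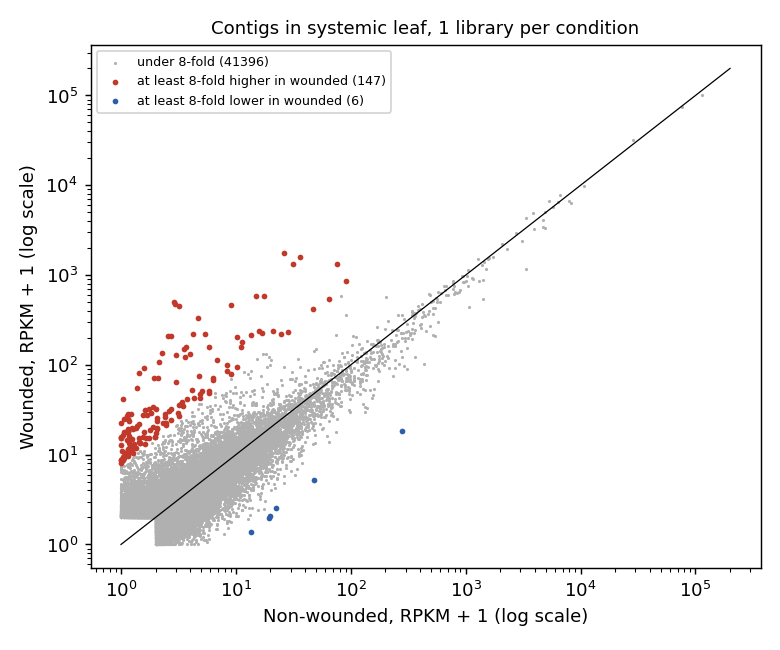
RPKM + 1 of each contig in the wounded (vertical axis) against the non-wounded library (horizontal axis), both on log scales, for contigs at 1 RPKM or more in either library; the line marks equal values. The 147 contigs at least 8-fold higher in the wounded library outnumber the 6 at least 8-fold lower.

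The share of contigs past 2-fold grew with abundance. Among contigs whose higher library lay between 1 and 5 RPKM, 5.10% were 2-fold higher and 3.39% 2-fold lower. Between 5 and 50 RPKM these shares were 11.9% and 8.72%, and at 50 RPKM and above they were 15.2% and 9.83%. The pseudocount shrinks the ratios of low contigs, so these shares do not rank true changes. The 30 most abundant contigs held 72.4% of the reads without wounding and 72.0% after it, and 29 of them differed by less than 2-fold. RPKM values of all other contigs were thus scaled by a total that a few contigs set, almost equally in both libraries.

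The second comparison concerned the small RNA classes. The 24 nt class, which in plants holds mainly the small interfering RNAs of DNA methylation, was the largest, with 45.2% of reads without wounding and 47.3% after it. The 21 nt class, the usual length of miRNAs, held 27.3% and 28.0%, a log2 ratio of 0.037 that turned to -0.0072 over distinct tags and to -0.018 without the miRNA families. The 18, 19 and 20 nt classes were all lower after wounding, at 0.760-, 0.817- and 0.861-fold, and together they went from 7.48% to 6.11% of reads. The 22, 23 and 25 nt classes were also lower, at 0.897-, 0.944- and 0.941-fold. The counting intervals of all these shares were at most 0.09 percentage points wide, which says nothing of the spread between plants.

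**Figure D2:**
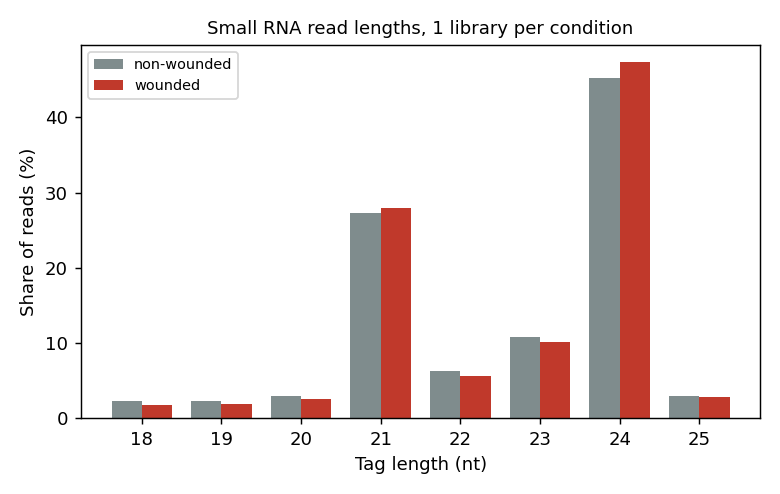
Share of small RNA reads (percent, vertical axis) at each tag length (nt, horizontal axis) in the non-wounded and wounded libraries, 1 bar per library. The 24 nt class held 45.2% and 47.3% and the 21 nt class 27.3% and 28.0%; the small difference in the 21 nt class reversed over distinct tags (log2 ratio -0.0072) and without the miRNA families (-0.018).

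The first base of the tags differed between the classes in the known way. Of 21 nt reads 81.2% (non-wounded) and 82.9% (wounded) began with U, the base that AGO1 prefers. Of 24 nt reads 71.9% and 74.7% began with A, the base that AGO4 prefers. Distinct tags showed the same order for 24 nt, with 67.8% and 70.2% beginning with A. Among distinct 21 nt tags U led with 37.9% and 39.5%.

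The third comparison asked which miRNA families differed. The 29 listed families held 17.1% of all small RNA reads without wounding and 18.1% after it, and 21 of them reached 100 reads. None of the 21 differed by 2-fold, and their log2 ratios ran from -0.31 to 0.34. With tags limited to 1 substitution miR169 passed 2-fold, at a log2 ratio of -3.35 from 10 reads and 1 read. The ratio was above 1 for 13 families and below 1 for 8. This tally turned with the rule and the scale: it was 10 and 11 with tags limited to 1 substitution, 9 and 12 scaled to family reads, and 19 and 2 scaled to family reads without miR166. Family reads without miR166 went from 6.98% to 6.36% of all reads, so that scale raises the ratio of every family. Of them 73.0% without wounding and 70.6% after it were miR398. In the main setting the counting interval lay above 1 for 6 families, below 1 for 4 and included 1 for 11. The 132 single tags with 1000 or more reads in either library had log2 ratios with an SD of 0.33 around a median of -0.10, and 3 of them passed 2-fold. The 112 of these tags in no family had a median of -0.14 (SD 0.34), and the 20 in a family a median of 0.15 (SD 0.20).

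miR166, which targets the HD-ZIP III leaf polarity factors, was the most abundant family, with 101411 RPM (reads per 1000000 small RNA reads) without wounding and 117373 after it, a ratio of 1.16 (1.15 to 1.16). Its leading tag, TCGGACCAGGCTTCATTCCCC, had 439232 and 518037 reads. miR403, which targets AGO2, was 1.19-fold higher (1.16 to 1.23), at 1707 and 2039 RPM. miR167, which targets auxin response factors, was 1.20-fold higher (1.12 to 1.29), and miR159, which targets GAMYB-type factors, was 1.13-fold higher (1.08 to 1.19). The ratio for miR159 rests on the tag TTTGGATTGAAGGGAGCTCCG, with 2313 and 2800 reads. With tags limited to 1 substitution, which leaves that tag out, the log2 ratio was -0.16. miR165, which differs from miR166 by 1 base, was 1.16-fold higher (1.04 to 1.29). Its exact sequence had 598 reads over both libraries and ranked 11 among the 63 possible single-base variants of the miR166 tag, whose other members had a median of 93. As 10 other variants had as many reads or more, miR165 cannot be told here from variants of miR166. It is nonetheless counted among the 6 families with intervals above 1.

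The families with intervals below 1 were miR397, miR398, miR396 and miR408. miR397 and miR408 target laccases and other copper proteins, and miR398 targets copper/zinc superoxide dismutases. miR397 had the lowest ratio, 0.807 (0.763 to 0.853), at 584 and 471 RPM. miR398 was the family second in abundance, at 50946 and 44905 RPM, a ratio of 0.881 (0.876 to 0.887). Nearly all of it was the tag TGTGTTCTCAGGTCGCCCCTG, with 241646 and 216992 reads. With tags limited to 1 substitution, which leaves that tag out, the log2 ratio of miR398 was -0.022. miR408 was at 0.946 (0.920 to 0.973). Its log2 ratio, -0.080, became -0.16 scaled to family reads and -0.13 with ends up to 3 nt from the reference. Scaled to family reads without miR166, which were 73.0% miR398 without wounding, miR408 had a log2 ratio of 0.056. Its 2 main lengths went opposite ways: the 21 nt tags had 5333 and 4604 reads, a ratio of 0.847 (0.814 to 0.881), and the 20 nt tags 4642 and 5013 reads, a ratio of 1.06 (1.02 to 1.10). miR396, which targets growth-regulating factors, was at 0.929 (0.915 to 0.942), whereas scaled to family reads without miR166 its log2 ratio was 0.029. Its tags differed: the leading tag TTCCACAGCTTTCTTGAACTT had 30219 and 27670 reads, whereas the exact reference sequence had 4763 and 5304.

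The intervals of the other named families included 1. They were miR156 and miR157 (SPL factors), miR160 (auxin response factors), miR162 (DCL1), miR168-3p, miR169 (NF-YA factors), miR319 (TCP factors), miR390 (the trigger of TAS3 siRNAs), miR393 (auxin receptors), miR399 (PHO2, in phosphate balance) and miR2111. Among them miR157 was the most abundant, at 3072 and 3078 RPM and a ratio of 1.00 (0.979 to 1.03). miR393 had the highest ratio, 1.26 (0.966 to 1.65), from only 101 and 130 reads. No tag was assigned to miR395, miR482 or miR828 in either library. For tags within the family rule this allows each up to 0.626 and 0.615 RPM. Variants outside the rule were not counted, so the families themselves are not bounded.

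**Figure D3:**
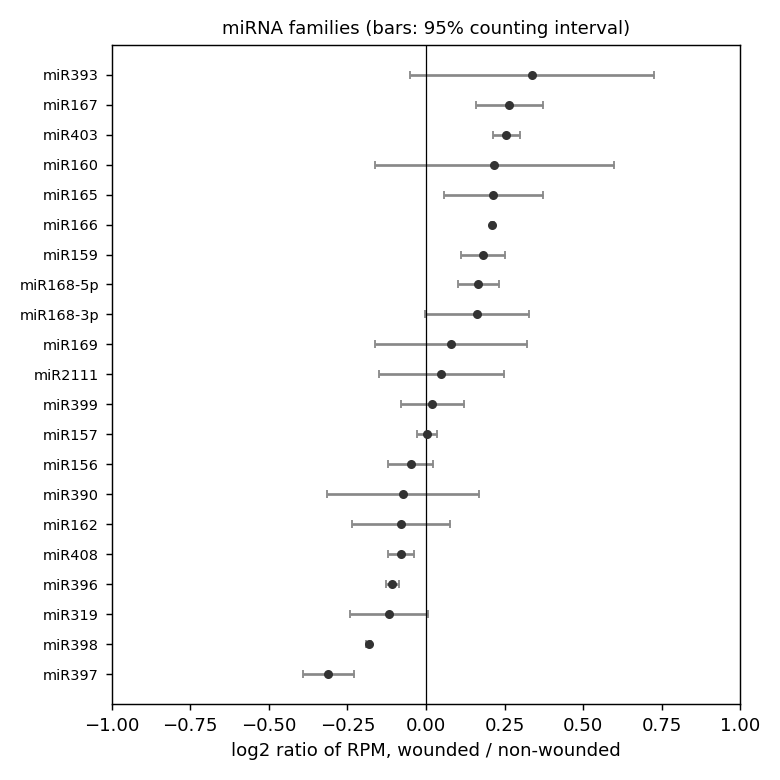
log2 ratio of RPM, wounded over non-wounded (horizontal axis), for each miRNA family with 100 or more reads in either library (vertical axis, ordered by ratio); bars are 95% intervals for counting error only. All families lie between -0.31 and 0.34, well inside the 2-fold limits of the axis.

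The last comparison concerned miR168, the miRNA of the series title, whose 5p strand targets AGO1. The tags counted as miR168-3p follow the reference sequence, and which tag the title means is not known here. miR168-3p was at 117 RPM (562 reads) without wounding and 131 RPM (641 reads) after it. The ratio was 1.12, with a counting interval of 0.998 to 1.26, so a difference was not detectable at this depth and a change of 2-fold or more lay outside the interval. Its leading tag, CCCGCCTTGCATCAACTGAAT, had 489 and 544 reads. A second tag, CCCGTCCTGTATCAATTGAAT, lies close to the reverse complement of miR168-5p and had more reads, 1246 and 1381. With it added, miR168-3p was at 378 and 414 RPM, a ratio of 1.10 (1.03 to 1.17). miR168-5p was at 749 and 841 RPM, a ratio of 1.12 (1.07 to 1.17). The 5p strand was 6.38 times as abundant as the 3p strand without wounding and 6.40 times after it, and this balance did not differ beyond counting error (3p over 5p changed by a factor of 0.997, interval 0.889 to 1.12). With the second tag counted as 3p, the 5p strand was 1.98 and 2.03 times as abundant. Within miR168-5p the tag TCGCTTGGTGCAGGTCGGGAA was 1.20-fold higher (1.12 to 1.28), and the tag TTCGCTTGGTGCAGGTCGGGA was at 1.02 (0.938 to 1.11). The log2 ratios of the 2 strands, 0.16 for 3p and 0.17 for 5p, lay near the median of the 20 abundant family tags, whereas 82.6% of all 132 abundant tags had a lower log2 ratio than either strand. The transcript of KTN80 was not analysed here, since the contigs carry no gene names.

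Among the 103 tags of 20 to 24 nt with 1000 or more reads, the lowest ratios were in tags assigned to no listed family. CCCAGTCCCGAACCCGTCGGCT went from 1957 to 842 reads, a ratio of 0.422 (0.389 to 0.458), and CCAGTCCCGAACCCGTCGGCT, the same sequence without its first base, from 4106 to 2069 reads. GGCGGACTGCTCGAGCTGCT was at 0.549, CCCTGTTGAGCTTGACTCTA at 0.606 and TTGAGTGTAGCGTTGATGAGA at 0.645. The last of these matches the miR397 reference within the substitutions allowed, but it is shifted by more than the 1 nt allowed. The highest ratios lay closer to 1. CTAACAGACCGGTAGACTTGA was 1.53-fold higher (1.40 to 1.66), TTTTGATCTTCGAAACCCAT 1.51-fold, GCACGTCTGCCTGGGCGTCACGC 1.45-fold, CTTCTGGTGTCCTAGGCGTA 1.33-fold, and the miR166 variant TTCGGACCAGGCTTCATTCCC 1.24-fold.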

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

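The 5 most abundant tags of 20 to 22 nt that belonged to no listed family carried reads far above the limit that a count of 0 allows, and the main comparison of families left them out. The tag TCTCGGACCAGGCTTCATTCC had 101042 reads without wounding and 112494 after it, a ratio of 1.09 (1.08 to 1.10). It is the miR166 sequence shifted by more than the 1 nt allowed, and it would be the third most abundant family by itself. With ends up to 3 nt from the reference it counts as miR166, whose log2 ratio was then 0.20 against 0.21. AGTTACTAATTCATGAGCTGGC had 37527 and 29557 reads, a ratio of 0.773 (0.761 to 0.785). TCACCGGCACTGCACTCAACC had 36200 and 29188 reads, a ratio of 0.791 (0.779 to 0.803). AACAGACCGGTAGACTTGAAC had 30630 and 29605 reads, and TAACAGACCGGTAGACTTGAAC 26981 and 25466 reads. The last 2 end in the same 18 bases.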

How the results depend on the processing

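Counts of contigs depended on the pseudocount and filter, and miRNA ratios on the scaling. Against 4561 contigs past 2-fold (2702 higher, 1859 lower), a pseudocount of 0.1 gave 12703 (7283 and 5420), a pseudocount of 5 gave 732 (505 and 227), and a minimum of 5 RPKM gave 1737 (1006 and 731). Settings added after seeing the data gave 10429 (6298 and 4131) with TPM, and 27036 (15163 and 11873) without the 30 most abundant contigs, where every other RPKM rises and more contigs pass the minimum. Contigs 16-fold higher numbered 273, 24 and 118 with pseudocounts of 0.1 and 5 and without the 30 contigs, against 51. Contigs 8-fold lower numbered 267, 1 and 36, against 6. At 8-fold, higher contigs outnumbered lower ones under every setting run, least with a pseudocount of 0.1 (805 against 267). No filter gave the same counts as the main one, since no contig under 1 RPKM can pass 2-fold with this pseudocount. Against a log2 ratio of 0.17 for miR168-5p, the exact sequence gave 0.26, scaling to family reads 0.087 and scaling to family reads without miR166 0.30. miR168-3p stayed inside its own counting interval under all 8 alternatives. Of the 21 named families 12 changed sign under at least 1 alternative. For 9 of them the main interval included 0, among them miR156 (0.087) and miR319 (0.017) scaled without miR166, miR393 (-0.17) and miR169 (-3.35) with 1 substitution, and miR2111 (-0.25) with the exact sequence. The other 3 were miR159 with 1 substitution (-0.16), miR396 with the exact sequence (0.13) or scaled without miR166 (0.029), and miR408 scaled without miR166 (0.056). Family reads without miR166 were 73.0% miR398 without wounding, and their share of all reads was lower after it. Scaling to them therefore raises the ratio of every family. The cause of the sign changes was otherwise not tested. The log2 ratio of the 21 nt share, 0.037, became -0.0072 over distinct tags and -0.018 without the miRNA families. That of the 24 nt share, 0.066, became 0.037 and 0.083. The table holds no lengths above 25 nt or below 18 nt, so the wider denominator gave no other value. FPKM, the gene lists, the KTN80 genes and the miRNA targets were planned and not run. No paired analysis was possible because each group holds 1 library, and no replicate could be left out for the same reason. Depth limits the families near 100 reads most: the interval of miR393 spans 0.966 to 1.65.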

Other observations

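All tests in this part were chosen after the results were seen, except that of GC content, whose limits were written down before its value was known. A total of 3 abundant tags outside the listed families lay close to the reverse complement of a family's leading tag, within an edit distance of 5, where shuffled tags gave 0.04 on average over the 51 tags searched. The limit of 5 was set after a first search at a distance of 7, which found 4 tags where shuffled tags gave 3.54, so the low number from shuffled tags at 5 is partly a product of that choice. GCTCTCTATGCTTCTGTCATC pairs with miR157 and was at 1.13 (1.04 to 1.22). GGGTCGGCATGAGAGCACATG pairs with miR398 and went from 6370 to 5190 reads, at 0.799 (0.771 to 0.829), beside 0.881 for miR398. CCCGTCCTGTATCAATTGAAT pairs with miR168-5p and went from 1246 to 1381 reads, at 1.09 (1.01 to 1.18). It had more reads than the tags counted as miR168-3p, and with it added the miR168-3p ratio was 1.10 (1.03 to 1.17).

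Tags were also grouped by their last 18 bases, and groups that held a tag of a listed family were left out. The largest remaining set, AGACCGGTAGACTTGAAC, held 132 distinct tags. It had 5.60% of all small RNA reads without wounding and 5.36% after it. Its 23 nt class, the most abundant, went from 122220 to 129818 reads and was the only one of its length classes with a higher share. The log2 ratio was -0.37 for its 18 nt class and -0.36 for its 24 nt class. Its tags were not mapped here. Of all tags seen in either library 13.2% were seen in both, and these held 66.6% and 66.3% of the reads.

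The excess of contigs that were 8-fold or more higher (147 against 6) was weighed first. Draws with counting error alone gave 0 such contigs. They treated reads as independent molecules, and with this pseudocount they gave 0 contigs even past 4-fold. The draws therefore argue only against counting error of independent reads. A scale set by the most abundant contigs cannot be the whole cause: the excess was 24.5 to 1, 23.3 to 1 with the median log2 ratio set to 0 (a shift of only 0.065), and 9.81 to 1 (353 against 36) without the 30 most abundant contigs. The share of reads outside those 30 contigs had a log2 change of only 0.019. Without them every other RPKM rises against the same pseudocount, so 9.81 to 1 does not measure scaling alone. The size of the excess thus depends on the setting, down to 3.01 to 1 with a pseudocount of 0.1. Wounding stays open as the biological explanation, and so does any other difference between the plants sampled, because each condition had 1 library.

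The smaller share of 18 to 20 nt reads after wounding was weighed second. A few abundant tags cannot account for it, since tags with under 100 reads had a log2 ratio of -0.30, against -0.29 for those with more. Tags were not mapped, so tags with few reads may come from the same RNAs as abundant ones. A few abundant RNAs thus stay open as an explanation. GC content cannot be the whole cause either, since reads with GC of 50% or less had a log2 ratio of -0.24, against -0.36 for the rest. Length-dependent recovery as the whole cause would have lowered 20 nt against 21 nt miRNA tags by 0.25, and the pooled difference was -0.035 (-0.068 to -0.0018, counting error only). The 13 families with enough reads ran from -0.35 for miR156 to 0.32 for miR408, with a median of 0.042 (SD 0.19) and 4 of them below 0. In 136 sets of tags with one 3' end, the long minus the short class had a median of 0.12 (quartiles -0.094 to 0.33). It was above 0 in 89 sets, and over all reads it was 0.32. The bootstrap interval of the median, 0.079 to 0.19, took the sets as independent. Many sets end 1 base apart along one sequence, so that interval is likely too narrow. A part due to length or RNA breakdown stays open, as does wounding.

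The copper-regulated families miR397, miR398 and miR408 were weighed last. Their mean log2 ratio was -0.19, and 3 of the 1330 possible sets of 3 named families had a mean as low. Within miR408 the 21 nt tags were at 0.847 and the 20 nt tags, with 4642 of its 9979 reads without wounding, at 1.06, so its smaller share does not hold for both lengths. The set of 3 families was picked after its values were seen, so its rank among the 1330 sets is no independent evidence. The 132 single tags with 1000 or more reads had a median of -0.10 (SD 0.33), and the 112 of them in no family -0.14. A log2 ratio of -0.19 thus lies within the spread of single abundant tags. A larger share of miR166 cannot be the whole cause: scaled to all reads outside miR166 the log2 ratios were -0.28 (-0.36 to -0.20), -0.16 (-0.16 to -0.15) and -0.054 (-0.094 to -0.013), with intervals for counting error only. Scaled to the family reads outside miR166 the log2 ratios were -0.17 for miR397, -0.047 for miR398 and 0.056 for miR408. Of those reads without wounding 73.0% were miR398, so these values do not bear on miR166. A common response of these families is a hypothesis that may deserve replicated libraries, since each condition had 1 library.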
